A study of Homo sapiens with 12 samples.

How the data were processed

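Mature microRNAs (miRNAs) were measured by small RNA sequencing in HEK293T cells, a human embryonic kidney cell line that carries the SV40 large T antigen. Cells had been transfected with an siRNA against Tudor-SN or with a control siRNA. The 12 libraries formed 2 groups in each of 2 sequencing runs, with 3 libraries per group and run. Per the labels' protocols, run 1 used an RNA fraction of short RNA, libraries purified from polyacrylamide and a NextSeq sequencer, and run 2 used total RNA, size selection on a Pippin Prep and a HiSeq sequencer. Both runs used TruSeq small RNA libraries, in which adapters are ligated to both RNA ends, with 12 cycles of PCR. Barcoded libraries were pooled in equal molar amounts, per the labels.

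The deposited table had 2588 mature miRNA entries and gave each library in several units. The authors' raw counts per mature miRNA were whole numbers and served for all main tests. The authors' normalized signal was the raw count divided by a single DESeq size factor per library, as the constant ratio of the deposited columns showed, and was used only for an alternative test. The deposited RPM values summed to between 999768 and 1000470 per library and were read only to check the counts. The authors' table also held an adjusted p-value and a log2 fold change per run for their own comparison of the siRNAs, per the file headers. The submitters' processing notes name Bowtie2 for run 1 and cutadapt, Bowtie2, DESeq2 and DESeq for run 2, without versions. The aligner settings, the genome build, the miRNA annotation and the handling of reads that match several miRNAs are not given in the sources used here. Every value column carried a sample name or a named comparison, and each was used for that sample or comparison.

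Totals below are counts assigned to mature miRNAs, not the full sequencing depth of a library. They ranged from 222452 to 1092713 in run 1 and from 927727 to 3140214 in run 2. A miRNA with 0 counts in a library could have had up to 3 counts, which is 2.75 to 13.5 CPM, the count scaled to the library total, in run 1 and 0.955 to 3.23 CPM in run 2. These floors cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

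Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test. Library sizes were scaled by TMM, and miRNAs were kept by filterByExpr with its minimum count of 10 and minimum total of 15. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Run 1 and run 2 were each fitted alone with the siRNA as the factor. A fit over all 12 libraries had the siRNA and the run as factors, and a further fit added their interaction to test the difference between runs. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries, and log2 fold changes are Tudor-SN siRNA against control siRNA with their standard errors. The labels do not say whether replicates, or the same-numbered libraries of the 2 runs, came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

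Lists of miRNA families, clusters, tissue markers and entries that overlap other noncoding RNA were fixed before the data were examined, as were the tests, the samples in each fit and the main alternatives. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and with fry. The miRNAs named were those of a fixed rule: per comparison, the 12 largest increases and the 12 largest decreases past the threshold whose libraries did not overlap between groups, the 10 most abundant miRNAs, and of each list the 4 most abundant tested members plus those past the threshold. Agreement of the runs was measured by Pearson and Spearman correlation across miRNAs and by Fisher's exact test of shared calls.

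Hairpin positions came from the GENCODE release 29 annotation of GRCh38, matched by miRNA name, and are not the authors' coordinates. Of the 2588 entries, 2585 matched a hairpin and 2401 matched exactly 1. Near-identical family members, such as let-7, miR-99a and miR-99b, miR-10a and miR-10b, miR-125a and miR-125b, and the miR-17 family, can share reads, so their separate values are uncertain. Mature sequences were not used here, so a planned test of internal CA and UA dinucleotides was not run on mature miRNAs.

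The tests were checked on simulated counts with the means and library sizes of these libraries. Every simulated miRNA had the same relative spread between libraries, with no outlying library, so the shares hold only for that setting. They rest on 16 to 28 changed miRNAs per fold and simulation. In the run 1 simulation, with 215 miRNAs tested, 76.9% of miRNAs changed 1.5-fold, 82.4% of those changed 2-fold and 100% of those changed 4-fold were recovered. In the run 2 simulation, with 388 tested, the shares were 63.2%, 95.5% and 100%. In the simulation of both runs, with 373 tested, they were 68.8%, 90.5% and 100%. False calls made up 0%, 0% and 5.6% of all calls in the 3 simulations.

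Alternatives were RLE scaling, library size only, upper quartile scaling, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of the most abundant miRNA, thinning of counts to the smallest library, limma on log2 of the authors' normalized signal plus 1, summing of same-numbered libraries over runs, and leaving out each library. Some alternatives were chosen after seeing the data: removal of entries that overlap other noncoding RNA, the list of these entries without miR-4454, TMM within each run, all alternatives for the arm of the hairpin, leave-one-out for the agreement of runs, and leave-one-out, library size only and the 10 CPM minimum for the difference between runs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.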

Results

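Small RNA was sequenced from HEK293T cells transfected with an siRNA against Tudor-SN or with a control siRNA, and reads were counted per mature miRNA. Tudor-SN, encoded by SND1, is a protein with nuclease domains that is found in RNA-induced silencing complexes. The series was designed to find the mature miRNAs that this endonuclease removes, a route its authors call TumiD. There were 3 libraries per siRNA in each of 2 runs. Run 1 was made from short RNA and run 2 from total RNA, with different size selection and sequencers. SND1 mRNA was not measured, so the knockdown itself was not checked by these data.

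In run 1 the counts assigned to miRNAs were 246159, 270191 and 222452 in control replicates 1 to 3, and 1092713, 796496 and 658568 in Tudor-SN replicates 1 to 3. In run 2 they were 927727, 1653077 and 1115569 in the controls and 3140214, 2838965 and 1710708 in the Tudor-SN libraries. Every Tudor-SN library therefore held more counts than every control library of its run, so depth and siRNA went together. Counts of replicates within each group differed by more than read-counting noise (chi-square per degree of freedom from 2.75 to 44.3), which separate preparations of the same RNA would also do. Run 2 Tudor-SN replicate 3 stood farthest from its group, at 44.3 and 25.6 against replicates 1 and 2, where all other pairs lay between 2.75 and 11.1. miR-10a-5p, which comes from the HOXB cluster, was the most abundant miRNA in every library. It held 56.4% ± 0.909 of counts in the run 1 controls and 48.5% ± 0.373 in the run 1 Tudor-SN libraries (SD, n = 3). In run 2 its share was 35.3% ± 0.941 in controls and 25.6% ± 1.47 in Tudor-SN libraries.

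The run 1 comparison asks which miRNAs were higher or lower after Tudor-SN siRNA. The largest increase was that of miR-1-3p, a miRNA of heart and skeletal muscle, from 10.7 ± 8.27 to 87.0 ± 9.59 CPM, a log2 fold change of 2.98 (SE 0.42, adjusted p = 2.4e-11 by edgeR). That control mean, from 5, 2 and 1 counts, lay below the control floors of 11.1 to 13.5 CPM, so the size of the rise is uncertain. miR-1-3p was too rare to be tested in run 2, with 7 counts over 6 libraries. miR-126-3p, which is encoded in an intron of EGFL7 and is abundant in endothelium, rose in run 1 from 63.2 ± 14.2 to 187 ± 18.2 CPM. miR-375, best known from pancreatic islets, rose from 294 ± 23.1 to 656 ± 54.3 CPM. miR-362-5p and miR-501-3p, which lie in introns of CLCN5 on the X chromosome, rose by 1.47 (SE 0.16) and 1.17 (SE 0.11) on the log2 scale. The deepest losses were those of miR-3960, from 90.0 ± 28.4 to 10.1 ± 4.41 CPM, and of miR-16-2-3p, from 99.6 ± 19.2 to 12.0 ± 0.479 CPM.

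Of 224 miRNAs tested in run 1, 48 were higher and 51 lower with Tudor-SN siRNA, and the others did not pass. TMM sets the bulk of miRNAs near no change (median log2 fold change -0.05 in run 1 and -0.02 in run 2). Higher and lower are therefore relative to the other miRNAs, and a rise or fall common to all miRNAs could not be seen. At least 2-fold changes were seen in 14 of the higher and 27 of the lower miRNAs. Libraries of the 2 groups did not overlap for 52.7% of tested miRNAs, against 10% by chance. Further large increases were those of miR-455-5p (1.29), miR-708-5p (1.21), miR-9-3p (1.17), miR-98-5p (1.1) and miR-17-5p (1.1). Further large decreases were those of miR-7641 (-2.72), miR-3130-3p (-2.31), miR-663a (-2.24), miR-4488 (-2.17), miR-3648 (-2.12), miR-25-5p (-2.10), miR-1291 (-2.06), miR-3651 (-1.98), miR-1248 (-1.86) and miR-1260a (-1.84). Among these decreases, miR-7641, miR-663a, miR-3648, miR-1291, miR-1248 and miR-1260a are on the list of entries that overlap other noncoding RNA. The authors' deposited table had 49 miRNAs higher and 38 lower at the same threshold in run 1, of which 48 and 36 were among those called here.

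Members of the miR-10, miR-99, miR-100 and miR-125 family, which held most of the counts, moved in both directions in run 1, with 3 higher, 3 lower and 1 not passing. On chromosome 19, miR-99b-5p (MIR99B at 51692612 to 51692681) rose from 8862 ± 1137 to 18853 ± 1376 CPM, and miR-125a-5p (MIR125A at 51693254 to 51693339) rose by 1.09 (SE 0.13) on the log2 scale. Both hairpins lie in an intron of SPACA6. On chromosome 21, miR-99a-5p (MIR99A at 16539089 to 16539169, in an intron of MIR99AHG) had a log2 fold change of -0.32 (SE 0.08). miR-125b-5p, which has hairpins on chromosomes 11 and 21, fell by 0.86 on the log2 scale (SE 0.13). Of the abundant members, miR-10a-5p changed by -0.24 (SE 0.04) and miR-10b-5p by 0.28 (SE 0.05). The family list did not pass (limma camera adjusted p = 0.685). These paralogs can share reads, so the separate values are uncertain.

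The let-7 family, which represses growth-promoting mRNAs, had 5 members higher, 1 lower and 3 not passing in run 1 (limma camera adjusted p = 0.0375, and adjusted p = 0.447 with an estimated correlation). let-7f-5p rose by 0.89 (SE 0.09), let-7g-5p by 0.91 (SE 0.13) and miR-98-5p by 1.1 (SE 0.19), whereas let-7c-5p, from the chromosome 21 cluster, fell by 0.51 (SE 0.16). The miR-17-92 and paralogous clusters, induced by MYC, had 7 of 9 members higher and 0 lower (adjusted p = 0.0044, and adjusted p = 0.447 with an estimated correlation). Among them miR-17-5p rose by 1.1 (SE 0.18), miR-18a-5p by 0.92 (SE 0.22) and miR-19a-3p by 0.72 (SE 0.12), and miR-25-3p was at 0.03 (SE 0.08). The miR-17 seed family had 3 of 4 members higher (adjusted p = 0.0417, and adjusted p = 0.456 with an estimated correlation), a call that library size alone ended (adjusted p = 0.054). All members of this family are also on the list of the miR-17-92 and paralogous clusters, and several are among the repressors of G1/S genes. These lists are therefore not separate results. Of the repressors of G1/S genes, 6 of 23 were higher and 1 lower, and the list did not pass by camera (adjusted p = 0.073). That list was drawn up knowing of the study's interest in the G1/S transition and may hold miRNAs the study picked from these libraries, so it is not independent evidence of a direction. Entries that overlap other noncoding RNA, such as fragments of tRNA, rRNA and snoRNA, had 10 of 11 members lower and 0 higher (adjusted p = 6.54e-05, and adjusted p = 0.0913 with an estimated correlation). Their share of counts was 1.47% ± 0.0870 in controls and 0.473% ± 0.0668 in Tudor-SN libraries. The most abundant was miR-4454, which has a sequence close to tRNA, and it fell from 13105 ± 872 to 3894 ± 551 CPM.

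The remaining lists of run 1 did not pass (camera adjusted p from 0.685 to 0.954). The miR-15/16, miR-30 and miR-23/24/27 lists had 0 members past the threshold, of 4, 5 and 5 tested. The miR-181 family had 1 of 3 higher and 1 lower, and the list of reported A-to-I edited miRNAs had 1 of 7 higher and 3 lower. For these last 2 lists the median and the mean had opposite signs (-0.25 and 0.05, and 0.05 and -0.11). The miR-29, miR-34 and miR-449 and miR-200 families had fewer than 3 tested members and 0 past the threshold. The miR-302 and miR-367, miR-371-373, 14q32 and C19MC clusters and the mirtrons had none tested. Adjusted over the list alone, the counts were the same for every list of run 1 except the repressors of G1/S genes, with 6 higher and 0 lower. Among markers of other cell types, the muscle marker miR-1-3p had 5, 2 and 1 counts in the controls and 105, 71 and 51 in the Tudor-SN libraries. The muscle marker miR-133a-3p did not move with it, with 0, 0 and 0 counts against 0, 1 and 0. The neural marker miR-9-5p was at 0.37 (SE 0.12) and passed, and miR-486-5p of red blood cells was at 0.22 (SE 0.15) and did not. Counts of miR-122-5p of liver and of miR-451a, miR-142-3p and miR-223-3p of blood were 0 in all 6 libraries. Under upper quartile scaling, which moved the median log2 fold change of all tested miRNAs from -0.05 to -0.24, 33 were higher and 69 lower. The calls of miR-99a-5p and let-7c-5p ended without control replicate 3 (-0.20) and without control replicate 1 (-0.28), and those of miR-10a-5p (-0.05), miR-99a-5p (-0.13) and let-7c-5p (-0.32) ended with no filter on low counts.

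**Figure D1:**
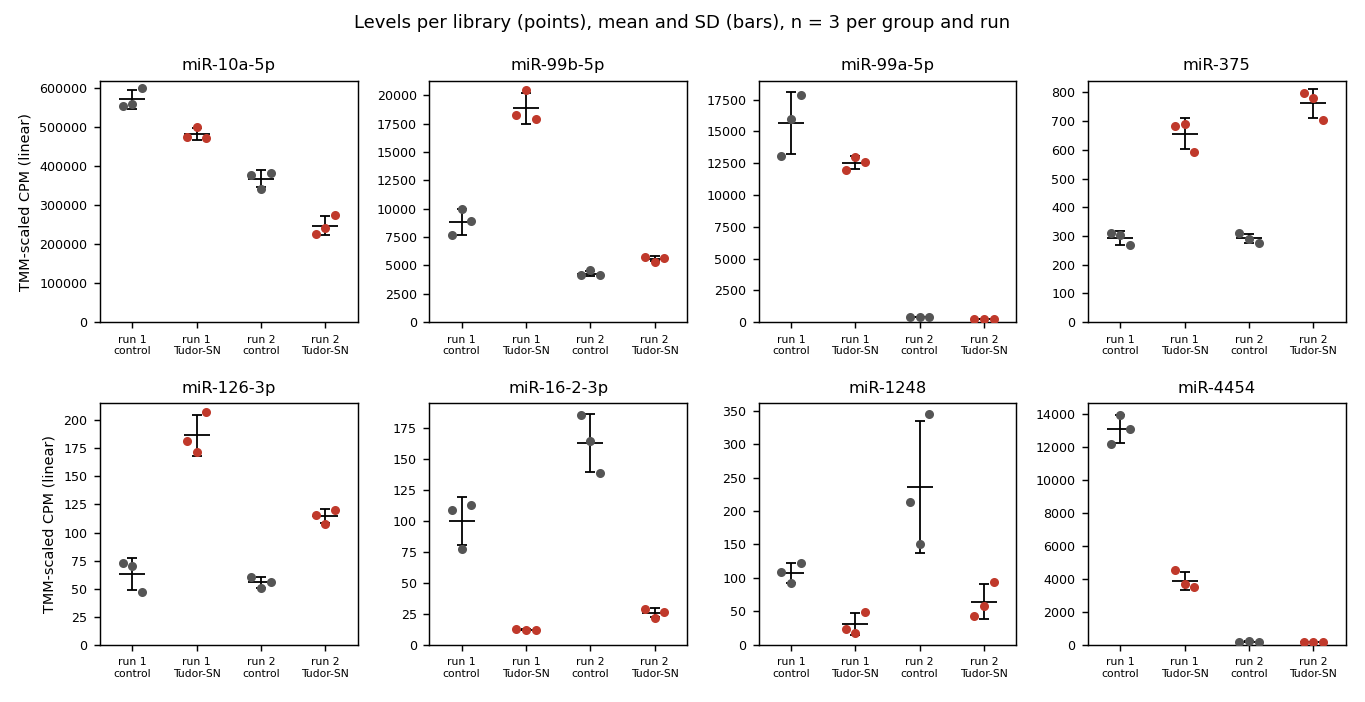
TMM-scaled CPM on linear axes for 8 miRNAs, with a point for each library and bars for the mean and SD (n = 3) of each siRNA and run. miR-375 lay near 294 and 292 CPM in the controls of runs 1 and 2 and at 656 and 761 CPM in the Tudor-SN libraries, while miR-16-2-3p fell to 12.0 and 25.6 CPM.

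Run 2 asked the same question in libraries from total RNA. miR-375 (MIR375, chromosome 2, 219001645 to 219001708) rose from 292 ± 16.3 to 761 ± 50.5 CPM, a log2 fold change of 1.39 (SE 0.08, adjusted p = 1.1e-09 by edgeR). miR-378a-3p, encoded in an intron of PPARGC1B, rose from 9627 ± 307 to 18938 ± 257 CPM, and the related miR-378c rose by 1.06 (SE 0.12). miR-126-3p (MIR126, chromosome 9, 136670602 to 136670686) rose from 55.8 ± 4.97 to 115 ± 6.24 CPM. miR-16-2-3p (MIR16-2, chromosome 3, 160404745 to 160404825, in an intron of SMC4) fell from 163 ± 23.4 to 25.6 ± 3.65 CPM, a log2 fold change of -2.66 (SE 0.15, adjusted p = 1.3e-09). miR-10a-5p fell from 367225 ± 22059 to 247299 ± 23827 CPM.

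Of 383 miRNAs tested in run 2, 92 were higher and 103 lower with Tudor-SN siRNA, and 188 did not pass. Changes of at least 2-fold numbered 15 among the higher and 32 among the lower. Groups did not overlap for 59.0% of tested miRNAs, against 10% by chance. The largest increases were those of miR-455-3p (1.91, from 2.88 to 9.83 CPM), miR-34c-5p (1.69), miR-33b-5p (1.63), miR-375, miR-548g-3p (1.33) and miR-320b (1.23). The control mean of miR-455-3p lay within the control floors of 1.81 to 3.23 CPM, so the size of its rise is uncertain. In run 1 miR-455-3p was at 0.33 (SE 0.34) and did not pass. After miR-16-2-3p the largest decreases were those of miR-195-3p (-2.39), miR-629-3p (-2.26), miR-4661-3p (-2.05), miR-3688-3p (-2.02), miR-1248 (-1.91), miR-365a-5p (-1.81), miR-125b-2-3p (-1.71) and miR-25-5p (-1.59). miR-629-3p and miR-629-5p (-1.38) come from the same hairpin in an intron of TLE3. Of the abundant miRNAs, miR-92a-3p rose by 0.31 (SE 0.06), while miR-10b-5p was at -0.18 (SE 0.08) and miR-191-5p at -0.01 (SE 0.06) and did not pass. The authors' deposited table had 88 higher and 68 lower in run 2, of which 85 and 68 were among those called here.

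The miR-17-92 and paralogous clusters had 8 of 10 members higher and 0 lower in run 2 (limma camera adjusted p = 0.0181, and adjusted p = 0.444 with an estimated correlation). miR-17-5p rose by 0.54 (SE 0.06), miR-106b-5p by 0.75 (SE 0.11) and miR-25-3p by 0.25 (SE 0.05), and the abundant miR-20a-5p was at 0.11 (SE 0.07). Of the repressors of G1/S genes, 14 of 31 were higher and 3 lower (adjusted p = 0.0181, and adjusted p = 0.39 with an estimated correlation), a list that is not independent of the study's interest. Its higher members included miR-34a-5p (0.64) and miR-34c-5p, targets of p53, and miR-126-3p, and its lower members were miR-449a (-0.92), miR-129-5p (-0.73) and miR-16-5p (-0.16). Entries that overlap other noncoding RNA had 9 of 13 members lower and 0 higher, and the list did not pass the camera test (adjusted p = 0.0619, and adjusted p = 0.39 with an estimated correlation). With the replicate number as a block the list passed by camera (adjusted p = 0.0284). The share of counts of these entries was 0.129% ± 0.00662 in controls and 0.0922% ± 0.00889 in Tudor-SN libraries. miR-1248, whose hairpin overlaps an exon of EIF4A2, fell from 236 ± 99.1 to 64.6 ± 26.1 CPM, and miR-4454 was at -0.26 (SE 0.10), a call that RLE scaling (-0.23) and library size alone (-0.15) ended.

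The let-7 family had 6 of 9 members higher and 1 lower in run 2 (camera adjusted p = 0.19), with let-7f-5p at 0.45 (SE 0.06) and let-7c-5p at -0.77 (SE 0.08). The miR-17 seed family had 3 of 5 higher (adjusted p = 0.1). The miR-10, miR-99, miR-100 and miR-125 family had 2 of 6 higher and 3 lower (adjusted p = 0.548): miR-99b-5p rose by 0.38 (SE 0.06) and miR-125a-5p by 0.32 (SE 0.07), while miR-99a-5p fell by 0.69 (SE 0.08) and miR-125b-5p by 0.94 (SE 0.12). In the miR-181 family miR-181c-5p rose by 0.86 (SE 0.09) and miR-181d-5p by 0.64 (SE 0.07), and miR-181a-5p (-0.22) and miR-181b-5p (-0.46) fell (adjusted p = 0.741). The miR-15/16 family had 3 of 7 higher and 1 lower, the miR-23/24/27 clusters 2 of 5 higher, the miR-30 family 1 of 5 higher, the miR-34 and miR-449 family 2 of 4 higher and 2 lower, the A-to-I edited list 2 of 9 higher and 2 lower and the miR-29 family 0 of 3. None of these lists passed by camera (adjusted p from 0.138 to 0.88). Fry does not set a list against the other miRNAs. By fry the miR-23/24/27 clusters (adjusted p = 0.00249) and the miR-29 family (adjusted p = 0.0428) passed as higher. The A-to-I edited list passed as lower (fry adjusted p = 0.0339). The let-7, miR-17 seed, miR-181 and miR-10, miR-99, miR-100 and miR-125 families also passed by fry (adjusted p from 0.0037 to 0.0418). The miR-200 family and the mirtrons had fewer than 3 tested members and 0 past the threshold, and the miR-302 and miR-367, miR-371-373, 14q32 and C19MC clusters had none tested. Adjusted over the list alone, the counts were the same except for the miR-15/16 family (4 higher, 1 lower), the miR-30 family (0 and 0) and the miR-10, miR-99, miR-100 and miR-125 family (2 higher, 4 lower).

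Among markers of other cell types in run 2, miR-486-5p rose by 0.20 (SE 0.06), miR-9-3p by 1.04 (SE 0.36) from 4.08 to 8.60 CPM, and miR-9-5p was at -0.01 (SE 0.07). The muscle miRNA miR-133a-3p had 0, 0 and 1 counts in the controls and 23, 11 and 16 in the Tudor-SN libraries and was too rare to be tested, and miR-1-3p had 1, 0 and 0 against 2, 3 and 1. Liver miR-122-5p and blood miR-451a had 1 count each over the 6 libraries. With library size alone, which moved the median log2 fold change from -0.02 to 0.08, 103 were higher and 78 lower. Without Tudor-SN replicate 3, 83 were higher and 96 lower.

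**Figure D2:**
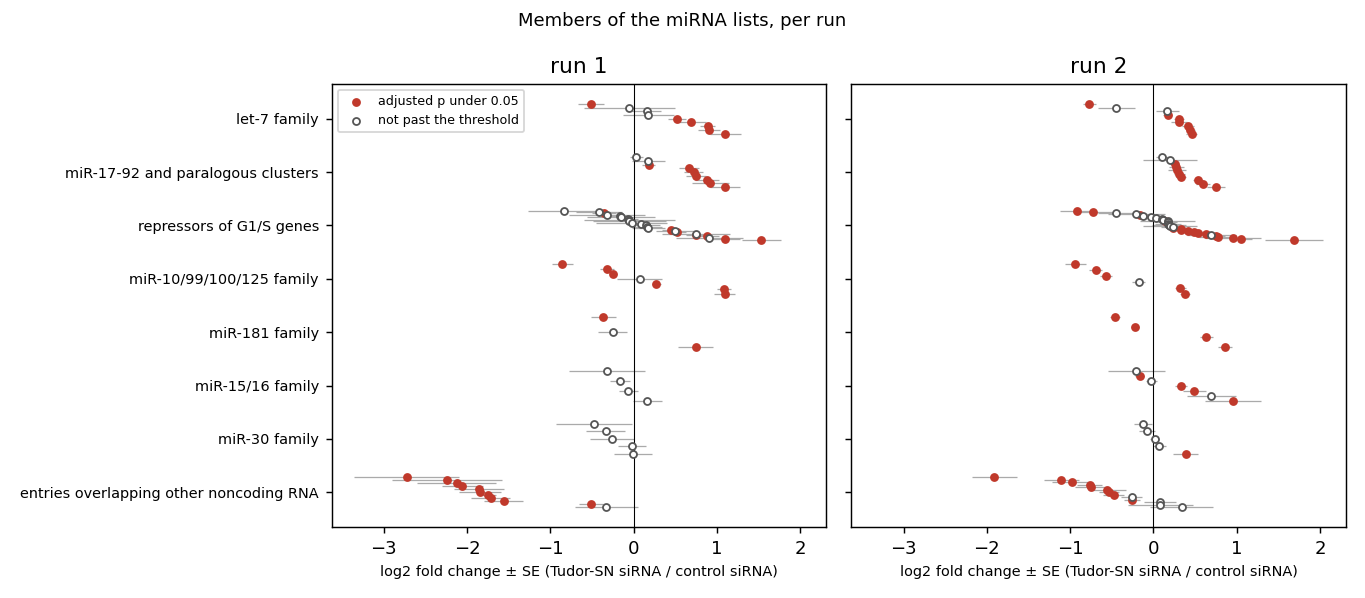
Log2 fold changes with their standard errors (horizontal axis) of the tested members of 8 lists (vertical axis), for run 1 on the left and run 2 on the right; filled points passed the threshold. Entries overlapping other noncoding RNA had 10 of 11 members lower in run 1 and 9 of 13 in run 2, and the miR-17-92 and paralogous clusters had 7 of 9 and 8 of 10 higher.

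The comparison of the runs asks whether they gave the same changes. Of 199 miRNAs tested in both, 34 were higher in both runs, against 16.5 for independent lists (Fisher's exact test, p = 3.9e-09). There were 31 lower in both runs, against 10.1 (Fisher's exact test, p = 2.21e-15). The shared increases included miR-375, miR-126-3p, miR-126-5p, miR-99b-5p, miR-17-5p and let-7f-5p, and the shared decreases included miR-16-2-3p, miR-1248, miR-25-5p, miR-629-5p, miR-3960 and miR-125b-5p. Only miR-3529-3p passed in both with opposite signs, at 0.29 in run 1 and -0.64 in run 2, and it is named because its values stood out. Across these miRNAs, which are not independent replicates, the log2 fold changes had a Pearson r of 0.747 and a Spearman rho of 0.703, and 75.9% had the same sign. The slope of run 2 on run 1 was 0.562.

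**Figure D3:**
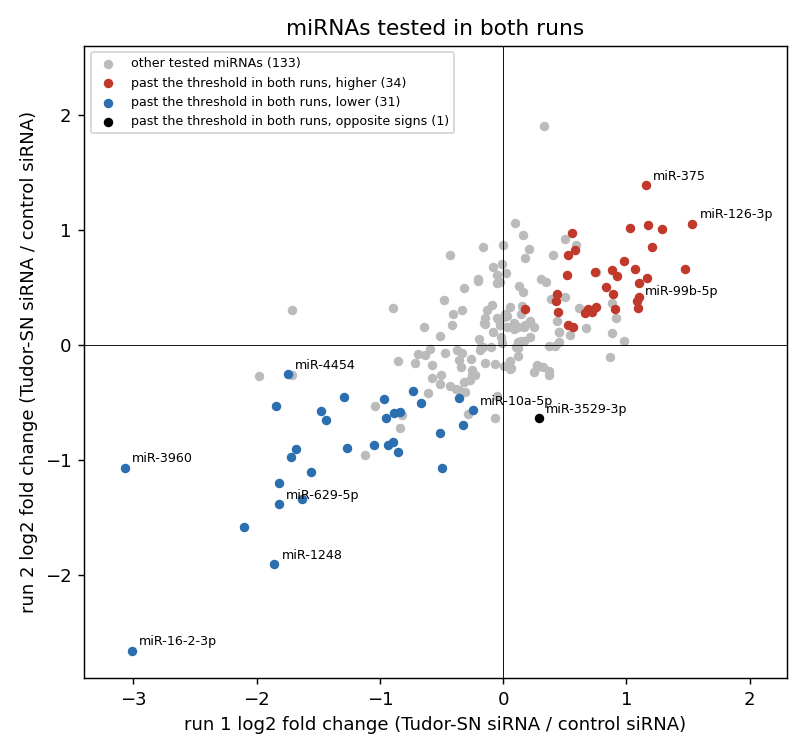
Log2 fold change in run 1 (horizontal axis) against run 2 (vertical axis) for the 199 miRNAs tested in both, with a point per miRNA. The 34 miRNAs higher in both runs lie at the upper right and the 31 lower in both at the lower left; miR-16-2-3p is at -3.01 and -2.66, miR-375 at 1.16 and 1.39.

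In the fit over all 12 libraries with the run as a factor, miR-375 rose by 1.44 (SE 0.09) and miR-16-2-3p fell by 2.59 (SE 0.17) on the log2 scale (adjusted p = 4.2e-11 for each by edgeR). Both values lay above those of runs 1 and 2 alone (1.16 and 1.39, and -3.01 and -2.66). The median log2 fold change of all tested miRNAs was 0.09 here and -0.03 with TMM within each run. Fold changes of this fit therefore depended on joint scaling and are not averages of the runs. Both arms of the miR-126 hairpin rose, miR-126-3p by 1.38 (SE 0.14) and miR-126-5p by 1.17 (SE 0.09), as did both arms of the miR-362 hairpin, miR-362-5p by 1.28 and miR-362-3p by 1.24. miR-548g-3p (1.62), miR-320b (1.47), miR-455-5p (1.24), miR-9-3p (1.23), miR-708-5p (1.12), miR-342-3p (1.03) and miR-365a-3p (1.02) were the other large increases. Large decreases were those of miR-629-3p (-1.72), miR-1248 (-1.72), miR-25-5p (-1.51), miR-3960 (-1.51), miR-629-5p (-1.41), miR-5096 (-1.30), miR-4634 (-1.28), miR-181b-3p (-1.28), miR-4661-5p (-1.17), miR-4485-3p (-1.17) and miR-6087 (-1.16). Among these decreases, miR-1248, miR-4485-3p and miR-6087 are on the list of entries that overlap other noncoding RNA. miR-1-3p was at 2.88 (SE 0.39), but its libraries overlapped between groups.

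Of 358 miRNAs tested over both runs, 107 were higher and 74 lower. Groups did not overlap in the same direction in both runs for 26.8% of them, against 0.5% by chance. That chance value holds only if the libraries of the 2 runs are separate samples, which the labels do not say. These counts depended on how the runs were scaled together, and those of list members below may too. With TMM within each run, an alternative chosen after seeing the data, 81 were higher and 90 lower, and without run 2 control replicate 1, 80 were higher and 84 lower. Thinning all libraries to the smallest gave 49 higher and 57 lower of 224 tested, and the sum of same-numbered libraries gave 92 higher and 121 lower. The miR-17-92 and paralogous clusters had 9 of 9 members higher (camera adjusted p = 0.0012, and adjusted p = 0.345 with an estimated correlation), and the miR-17 seed family 4 of 4 (adjusted p = 0.0277, and adjusted p = 0.345 with an estimated correlation). The let-7 family had 6 of 9 higher and 1 lower (adjusted p = 0.0387, and adjusted p = 0.41 with an estimated correlation). Calls of the let-7 and miR-17 seed lists ended under RLE scaling (adjusted p = 0.072 and 0.0505), and that of let-7 also with a replicate block (adjusted p = 0.0535). Of the repressors of G1/S genes 15 of 28 were higher and 1 lower (adjusted p = 0.0237, and adjusted p = 0.345 with an estimated correlation). Entries that overlap other noncoding RNA had 10 of 14 lower and 0 higher (adjusted p = 0.0012, and adjusted p = 0.345 with an estimated correlation). The other lists did not pass by camera (adjusted p from 0.588 to 0.955). Adjusted over the list alone, the counts were the same except for the repressors of G1/S genes, with 15 higher and 2 lower.

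Mature miRNAs from the 5p arm of the hairpin did not differ from those of the 3p arm in run 1, in run 2 or over both runs by camera in limma at the 0.05 threshold. In run 1, 25 of 99 miRNAs named 5p and 19 of 96 named 3p were higher (Fisher's exact test, p = 0.395), and 16 and 19 were lower (p = 0.577). In run 2, 47 of 162 and 37 of 160 were higher (Fisher's exact test, p = 0.254), and 39 and 43 were lower (p = 0.61).

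The interaction of siRNA and run was tested for 378 miRNAs, and 34 passed, with 21 more positive and 13 more negative in run 2 than in run 1. miR-125a-5p, miR-99b-5p and miR-20a-5p rose less in run 2 than in run 1 or did not pass there, with differences of -0.72 (SE 0.13), -0.65 (SE 0.12) and -0.72 (SE 0.18). miR-4454, miR-1260b, miR-1291 and miR-3960 had a less negative or more positive change in run 2, with differences of 1.54 (SE 0.14), 1.5 (SE 0.27), 2.90 (SE 0.58) and 2.06 (SE 0.41). These 7 passed under each of the 17 alternatives in which they had an adjusted p-value. The balance of directions did not hold: 10 were more positive and 34 more negative under RLE scaling, 13 and 31 with TMM within each run, 8 and 55 with a minimum of 10 CPM, and 67 and 7 without run 2 Tudor-SN replicate 3.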

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

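The test of the difference between runs was chosen before the data were examined, while its alternatives of library size only, a minimum of 10 CPM, TMM within each run and leaving out each library were chosen after the results were seen. Each result here stood out because the change after Tudor-SN siRNA differed between run 1 and run 2 by the interaction test in edgeR. Groups of 3 libraries are too small for a test of single outlying libraries.

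In all, 34 of 378 miRNAs differed between runs. Of the miRNAs named by the fixed rule, those with a less positive or more negative change in run 2 were let-7f-5p (-0.40, SE 0.11), let-7g-5p (-0.55, SE 0.13), miR-98-5p (-0.64, SE 0.20), miR-20a-5p (-0.72, SE 0.18), miR-125a-5p (-0.72, SE 0.13), miR-99b-5p (-0.65, SE 0.12), miR-10b-5p (-0.40, SE 0.10), miR-182-5p (-0.36, SE 0.11), miR-191-5p (-0.38, SE 0.11), miR-501-3p (-0.53, SE 0.14) and miR-629-3p (-1.49, SE 0.49). Those with a more positive or less negative change in run 2 were miR-27b-3p (0.69, SE 0.14), miR-378a-3p (0.47, SE 0.10), miR-1260a (1.36, SE 0.28), miR-1260b (1.5, SE 0.27), miR-4454 (1.54, SE 0.14), miR-6087 (1.92, SE 0.60), miR-3960 (2.06, SE 0.41) and miR-1291 (2.90, SE 0.58). Of these, miR-1260a, miR-1260b, miR-4454, miR-6087 and miR-1291 are on the list of entries that overlap other noncoding RNA. miR-6087 and miR-629-3p were not tested in run 1 alone, and miR-1291 was not tested in run 2 alone. Of the 19 miRNAs named here, 12 lost their call under 1 or more alternatives. Among them was miR-378a-3p, whose difference was -0.0153 without run 1 Tudor-SN replicate 3.

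The runs differed in RNA fraction, size selection and sequencer at once, so none of these can be named as the cause, and no biological explanation was tested. Of 100 splits of the libraries within runs, 8 gave as many calls as the real 34, and the highest other split gave 146. That split exchanged the siRNA labels in run 2 only, so it carries the effect that the runs share. Splits that keep part of the real grouping carry it too, so this count is not one of chance alone and decided nothing about the number of differences.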

How the results depend on the processing

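TMM within each run, removal of entries that overlap other noncoding RNA, and library size only, the 10 CPM minimum and leave-one-out for the difference between runs were chosen after the results were seen. Of named miRNAs past the threshold, 40 of 53 in run 1, 57 of 77 in run 2, 47 of 74 over both runs and 7 of 19 for the difference kept their call under every alternative in which they had an adjusted p-value. An alternative that left a miRNA untested was not counted as a lost call. miR-375 ranged from 0.96 to 1.35 in run 1 and from 1.34 to 1.51 in run 2, and miR-16-2-3p from -3.20 to -2.70 and from -2.77 to -2.53. Named values that lost their call numbered 54, 97, 115 and 63 in these fits. Leaving out each library gave 41 to 48 higher and 48 to 53 lower miRNAs in run 1, 77 to 89 and 83 to 100 in run 2, and 80 to 100 and 74 to 84 over both runs.

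With an estimated correlation, 0 lists passed in run 1 (4 with the preset), 0 in run 2 (2) and 0 over both runs (5). Some of these lists share members, so they are not separate results. With fry 10 lists passed in run 2, and with RLE 3 over both runs. Over both runs, thinning of counts gave 49 higher (57 lower), with fewer miRNAs tested (224 against 358), and the sum of same-numbered libraries gave 121 lower (92 higher). The difference between runs had 63 miRNAs with a minimum of 10 CPM and 23 to 74 with each library left out. Signs reversed for miR-92a-3p in run 1 under upper quartile scaling (-0.0134), and over both runs for miR-30c-5p with thinned counts (-0.51) and for miR-10b-5p (-0.044), miR-191-5p (-0.079), miR-16-5p (-0.24) and miR-99a-5p (0.13) with summed libraries. In runs 1 and 2 alone miR-30c-5p (-0.26 and -0.12) and miR-16-5p (-0.06 and -0.16) were negative, so for them the main joint fit stood apart. miR-99a-5p was also negative in each run alone (-0.32 and -0.69), so for it the summed libraries stood apart. That sum had no run factor. The difference between runs of miR-378a-3p ranged from -0.0153, without run 1 Tudor-SN replicate 3, to 0.69, without run 2 Tudor-SN replicate 3. Except for the fewer miRNAs tested, the cause was not tested. In run 2, no filter gave 106 higher and 77 lower.

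With the replicate number as a block, 50 were higher and 58 lower in run 1, 90 and 108 in run 2, and 94 and 68 over both runs, and 4, 3 and 4 lists passed: the noncoding RNA list passed in run 2 (adjusted p = 0.0284, against 0.0619 without the block, and adjusted p = 0.39 with an estimated correlation), and let-7 no longer passed over both runs (adjusted p = 0.0535). Correlations between libraries were taken on deviations of log2 CPM from the mean of each group and run, not on levels. Same-numbered control and Tudor-SN libraries had correlations of 0.143, 0.140 and 0.0814 in run 1 and 0.0439, 0.0526 and 0.0720 in run 2, so the numbers were not taken to pair samples. In run 1 each library correlated best with its own number, in run 2 not. Between runs, same-numbered Tudor-SN libraries had correlations of 0.249, 0.228 and 0.324, above their other pairings, and controls 0.0481, -0.105 and -0.235, with other control pairings of up to 0.242, so shared cultures of the runs were not excluded. The alternatives on CA and UA dinucleotides were not run, because no mature sequences were used here.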

Other observations

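The arms of single hairpins moved together in some cases and apart in others. miR-16-2-3p was among the largest decreases of both runs, while miR-16-5p, which comes from this hairpin and from MIR16-1, was at -0.06 (SE 0.11) in run 1 and -0.16 (SE 0.05) in run 2. miR-25-5p fell in both runs, and its partner miR-25-3p, of the MCM7 intron, was at 0.03 (SE 0.08) and 0.25 (SE 0.05). Both arms of the miR-126 hairpin rose, with miR-126-5p at 1.03 (SE 0.15) in run 1 and 1.02 (SE 0.07) in run 2. These arms were singled out after their values were seen.

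Tests of 5 ideas were run on the libraries already reported, so their results are hypotheses only. The tests of passenger arms of paralogs and the use of run 2 against background in run 1 controls were chosen only after the results were seen.

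Entries that overlap other noncoding RNA passed as a list in run 1 with the preset correlation (with an estimated correlation adjusted p = 0.0913 by limma camera) and did not pass in run 2 by camera (adjusted p = 0.0619). In run 2 the replicate number as a block gave a camera adjusted p of 0.0284, and an estimated correlation gave 0.39. With counts thinned to the smallest library the list median was -1.72 in run 1, with 7 of 8 members past the threshold. In run 2 it was -0.62, with 7 of 11 past it. Thinning keeps the expected share of each entry in its library, so this outcome was largely fixed in advance. Thinning showed only that the fall remained at equal numbers of counts, and differences that went with depth were not excluded. Background of the run 1 controls stayed open, although the median in run 2 was -0.54 (limma fry adjusted p = 0.00344). By the interaction test miR-4454, miR-1260a, miR-1260b, miR-1291 and miR-6087 had a less negative or more positive change in run 2. Part of the fall was therefore particular to run 1. The interaction calls of miR-1260a and miR-6087 did not hold under every alternative. Fragments of other RNA carried over at library preparation could still differ between the groups, because thinning to -1.72 does not address preparation, which went together with the siRNA.

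The paralogous clusters on chromosomes 19 and 21 moved apart. In run 2 their passenger arms differed by 1.41 (SE 0.264; 3 arms against 2), and the difference came from chromosome 21, at -1.36 (SE 0.19), with miR-125b-2-3p at -1.71 and miR-99a-3p at -1.01 from 37 and 41 counts. Across 80 hairpins of run 2 the changes of the 2 arms had a Pearson r of 0.464, so an arm need not track its partner. The fall of these passenger arms therefore decided nothing about shared reads for the guide arms. On chromosome 19 the 3 passenger arms averaged 0.0448 (SE 0.183) with none past the threshold. The run 2 guide arms miR-99b-5p, let-7e-5p and miR-125a-5p of chromosome 19 rose (0.38, 0.46 and 0.32, SE 0.06, 0.07 and 0.07). The guide arms miR-99a-5p, let-7c-5p and miR-125b-5p fell (-0.69, -0.77 and -0.94, SE 0.08, 0.08 and 0.12). Reads shared in a fixed proportion between the 2 clusters would draw these changes together. The opposite signs argue against such sharing as their cause in run 2. Their sizes stayed uncertain, and sharing with other family members was not tested. Run 1 had too few passenger arms. Hairpins of the same cluster were closer in log2 fold change than permuted ones (1-sided permutation p = 0.0098 for 15 clusters in run 1 and p = 0.0063 for 24 clusters in run 2). A change in the shared transcript may contribute to these results, given the permutation p of 0.0098 and 0.0063, and primary transcripts were not measured here.

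A difference between minor and major arms of the same hairpin did not pass its test: the median difference was -0.19 in run 1 (sign-flip permutation p = 0.103, 33 hairpins) and -0.09 in run 2 (p = 0.233 by the same permutation, 80 hairpins). With thinned counts it was -0.25 over 18 hairpins and -0.0697, after removal of the GC trend it was -0.15 and -0.10, and 96.4% and 57.5% of sets matched on abundance were as low. As the pattern itself was not established, these values decided nothing. The density of CA and UA dinucleotides in the hairpin arm was a stand-in for the mature sequence. Its Spearman rho with the log2 fold change was 0.0454 in run 1 (permutation p = 0.538, 195 miRNAs) and 0.00298 in run 2 (permutation p = 0.955, 321 miRNAs). Neither passed. The density of a whole hairpin arm does not measure internal sites of the mature miRNA, so cutting at these dinucleotides was left open.

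Other splits of the libraries into groups were tested for chance. In run 1, 1 of 10 splits, the real one, called as many as 99 miRNAs, and in run 2, 1 of 10 called as many as 195, with 0 calls in every other split, but 10 splits are too few for a share under 0.05. Over both runs 1 of 100 splits called as many as the real 181, and the next highest called 51, which excludes chance only if the libraries of the 2 runs are separate samples. If same-numbered libraries were the same cultures, there would be 10 splits, too few again.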
